A study of Mus musculus with 63 samples.

How the data were processed

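RNA and open chromatin were measured in mouse fibroblasts (MEFs), in factor-transduced pools on day 3, and in established stem cell lines. Sample groups came from the labels. The 63 libraries fell into 30 groups, with 14 ATAC libraries, 15 day-3 and reference RNA libraries, 14 libraries each of the iPSC and iTSC experiments, and 6 chromatin immunoprecipitation libraries that were not analysed here.

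The day-3 values were FPKM that the authors deposited in 1 table, from 3′ single-end libraries aligned with TopHat and summarised with Cufflinks on mm9, per the labels' protocols and the submitters' processing notes (versions not given in the sources used here). The table held 1 pooled FPKM column per group, so the planned limma fit on separate libraries could not be made and differences of log2(FPKM + 1) between pools are given without a test. Of 23309 entries, 27 with date-like names were left out, and 11913 genes with a mean FPKM of at least 1 were kept. A gene was singled out at a difference of at least 2 on the log2 scale (4-fold). To set a list's median in context, its percentile among 10000 random lists of the same size, matched over 20 expression bins, was taken for lists with at least 5 measured members. Relative depth came from the commonest ratio of low values between pools. The reference ESC and TSC libraries came from another laboratory and kit and are shown for scale only.

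The established lines came as 2 deposited tables of raw counts per gene, made by the authors with cutadapt 1.12, TopHat2 2.0.14 and HTSeq 0.6.0 on GRCm38, per the submitters' processing notes, which also name DESeq2 1.16.1. The DESeq2-normalised tables and 1 browser track that matched no label were not used. Of 40914 gene identifiers, 40417 matched a symbol, and no entry lacked a gene. Libraries of 1 clone or line were summed. MEF libraries were kept apart because no label names lines or litters, so they may be repeats of 1 culture. Each group thus had 2 samples. Counts were tested with edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr and the quasi-likelihood test on all groups of a table in 1 fit, at a Benjamini-Hochberg adjusted p under 0.05 (17731 and 15767 genes tested). Levels are CPM, counts scaled to the library size. A fold against a group without any count is a lower bound, taken against a floor of 3 counts over the group. Floors and intervals cover counting error only. Libraries held 8488610 to 14218422 counts in the iPSC table and 2778189 to 9163435 in the iTSC table. Gm42418, which overlaps ribosomal RNA sequence, took 3.90 to 11.9% and 2.00 to 8.83% of them, and mitochondrial genes took 8.86% in ESC library v6-5_1 and 2.65 to 4.18% in the other ESC libraries, 4.04 to 7.02% in the iPSC libraries and 1.86 to 6.09% in the libraries of the iTSC table.

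The ATAC files were peak lists, 1 per group (how its libraries were combined is not given in the sources used here), made by the authors with Bowtie and MACS2 on mm9, per the submitters' processing notes (settings, versions and any read shift not given in the sources used here). Each peak has the authors' score, deposited in steps of 10 from 50, and it was used only to rank peaks within a list. The fold and p columns held 0 throughout and were not used. The list taken as iPSC from the labels is called ESC in its track header and by 1 of the 2 iPSC labels, and the list taken as iTSC is called iTSC in its header and TSC in its name. Peaks sharing at least 1 bp were counted as overlapping, 2 peaks per list were left out, and shares have exact (Clopper-Pearson) 95% intervals. No genome came with the data, so a peak was given to a gene within 5 kb of the gene's span in the day-3 table, where start sites had been planned.

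There were 18 gene lists: fibroblast and mesenchymal, epithelial, pluripotency, trophoblast stem, differentiated trophoblast, extraembryonic endoderm, proliferation, ribosome biogenesis and Myc targets, p53 response and senescence, cytokine and inflammatory, interferon response, imprinted, 2-cell-like, germline, germ layer and primed, other cell types, sex-linked, and reprogramming factors. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. The groups, lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 6 largest rises and 6 largest falls among called genes whose samples do not overlap between the groups and whose higher group mean is at least 10 CPM or FPKM, leaving out predicted, Rik, -ps and mitochondrial symbols. To these it added the 3 members of each list with the smallest p (the largest difference on day 3), the 8 factor genes and the reporter genes Nanog, Elf5 and Utf1. Comparisons outside the main ones took the first 3 of the largest changes.

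Alternatives were DESeq2 1.42.0, relative-log size factors, no filter on low counts, single libraries as samples with and without a block for library number, fits of only the groups compared, leaving out each clone, line or MEF library, a pseudocount of 0.1, FPKM filters of 5 or none, quantile normalization of the FPKM columns, and stricter overlaps and scores. A lone sample left in a group was assumed to vary like the other groups. Added after seeing the data were fits without Gm42418 and mitochondrial genes, without ESC library v6-5_1, without iTSC library 32, and without MEF library 1 and library 32. The count test was tested on simulated counts with 100 genes each at 2-fold and 4-fold. No other gene was changed, and the baseline of each gene was its mean over all groups. The rates of recovered and false calls may thus not hold where far more genes were called, as against MEF. Per comparison 35 to 53 and 74 to 86 of them were recovered for the iPSC experiment, and 0 to 6 and 36 to 51 for the iTSC experiment. Genes without a simulated change were called too, 7 to 15 per comparison for the iPSC experiment and 0 to 7 for the iTSC experiment. The share of such false calls was above the adjusted p threshold in each iPSC comparison and for GETMS iTSCs against MEF. It was below the threshold in the other iTSC comparisons. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.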

Results

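To study how fibroblasts take on the cell fates of the early embryo, mouse embryonic fibroblasts (MEFs) had been transduced with sets of transcription factors and profiled early, on day 3, and as established lines. GETM stands for Gata3, Eomes, Tfap2c and Myc, a set built around trophoblast regulators. GETMS adds Esrrb, GTMS is GETMS without Eomes, and OSKM is the classical set of Oct4 (gene symbol Pou5f1), Sox2, Klf4 and Myc. The data comprised 63 libraries. The day-3 RNA set held 2 libraries each of MEF, OSKM, GTMS and GETM pools and of GETMS pools kept in embryonic stem cell (ESC) medium or in trophoblast stem cell (TSC) medium, with 1 ESC and 2 TSC libraries re-analysed from elsewhere. Open chromatin had been profiled by ATAC-seq in 14 libraries, and 28 libraries covered established lines. These were induced pluripotent stem cells (iPSCs) from GETMS and OSKM, induced trophoblast stem cells (iTSCs) from GETM and GETMS, and ESC, TSC and MEF controls. The 6 histone-mark libraries were not analysed here.

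The day-3 table gave 1 pooled FPKM value per group, so no day-3 difference had a replicate check and none was tested. Absolute depth was unknown for this table. The step between low values put the pools at 1.2 (OSKM), 0.911 (GTMS), 1.05 (GETM), 1.01 (GETMS, ESC medium) and 1.14 (GETMS, TSC medium) times the depth of the MEF pool. The count table of the iPSC experiment held 8488610 to 14218422 counts per library and that of the iTSC experiment 2778189 to 9163435. In both tables, 2 libraries of 1 clone or line were summed, so each group had n = 2 clones, lines or MEF libraries. For the iTSC table this pairing was read by analogy with the iPSC names. The labels do not say that clones came from separate fibroblast cultures, or that the 2 MEF libraries of a table did. The p-values thus measure the spread between these clones, lines and MEF libraries, estimated over all groups of a table in 1 fit. To look for duplicates, libraries were compared only within a group of a count table, not between groups or tables. None of these pairs were identical or differed by as little as sampling noise (chi-square per degree of freedom 6.83 or more). No library was counted as a duplicate. Libraries of 1 line were not always the closest. This value was 133 between v6-5_1 and v6-5_2, 42.4 between BYKE_1 and BYKE_2, and 15.6 between BYKE_1 and v6-5_2.

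The factor genes were examined first. In the OSKM pool Pou5f1 stood at 787 FPKM, Sox2 at 110 FPKM and Klf4 at 531 FPKM, compared to 0.0604, 0.211 and 47.7 FPKM in MEF. Gata3 was between 1064 and 1325 FPKM in the 4 pools that received it and at 3.58 FPKM in MEF, and Tfap2c lay between 493 and 690 FPKM, compared to 0.315 FPKM in MEF. Eomes reached 926 FPKM in GETM, 786 FPKM in GETMS in ESC medium and 1265 FPKM in GETMS in TSC medium. It was at 8.97 FPKM in GTMS, which lacked the factor, and at 1.19 FPKM in MEF. Myc was 990 FPKM in OSKM and 963 to 1806 FPKM in the other pools, compared to 96.4 FPKM in MEF. Esrrb was 187 FPKM in GTMS and 169 and 180 FPKM in the GETMS pools. In GETM, which did not receive it, Esrrb was 18.7 FPKM, compared to 0.0830 FPKM in MEF. These values do not separate introduced from endogenous transcripts. Of 3 reporter genes, Nanog was at 1.97 FPKM in OSKM and 280 FPKM in the reference ESC library, and Elf5 stayed at or below 0.272 FPKM in every MEF and day-3 pool and was 107 FPKM in reference TSCs. Among the MEF and day-3 pools, Utf1 was highest in GETM at 5.54 FPKM compared to 0.0248 FPKM in MEF.

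To ask how far each pool had moved from MEF by day 3, gene lists fixed in advance were compared on the log2(FPKM + 1) scale, which understates differences of low genes. The FPKM filter kept 37 of 38 fibroblast, 16 of 30 epithelial, 16 of 32 pluripotency and 18 of 27 trophoblast stem genes. It kept 8 of 28 differentiated trophoblast genes and 10 of 29 markers of other cell types. It used the mean over the MEF and day-3 pools, so a factor gene could pass through the pools that received it. Medians and counts describe the kept members only. The median of the fibroblast and mesenchymal genes was lower in every pool. Of 37 measured genes, 9 were at least 4-fold lower in OSKM, 15 in GTMS, 19 in GETM, 25 in GETMS in ESC medium and 31 in GETMS in TSC medium. Their median log2 differences were -1.48, -1.78, -2.02, -2.24 and -3.21, each below all 10000 random lists of matched expression. Lox, which crosslinks collagen, was 693 FPKM in MEF, 49.6 in GTMS, 19.4 in GETM, 26.7 in GETMS in ESC medium and 3.12 in GETMS in TSC medium. Epithelial genes had medians of 0.63 in OSKM, 0.76 in GTMS, 1.95 in GETM, 1.59 in GETMS in ESC medium and 1.69 in GETMS in TSC medium (16 genes; percentiles 98.8 to 100). Of these, 7, 7, 11, 10 and 10 were at least 2-fold higher and 3, 3, 2, 2 and 2 at least 2-fold lower. The keratin Krt8 was 14.1 FPKM in MEF, 16.7 in GTMS, 122 in GETM and 245 in GETMS in TSC medium. The tight-junction gene Cldn4 was 0.723 FPKM in MEF and 47.6 to 143 FPKM in the 4 trophoblast-factor pools, and Cdh1 (E-cadherin) was 37.0 FPKM in GETMS in ESC medium compared to 0.574 FPKM in MEF.

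Pluripotency genes separated OSKM from the other pools. Of the 32 listed, 16 were measured. In OSKM 9 of these 16 were at least 4-fold higher than in MEF, among them the introduced Pou5f1, Sox2 and Klf4. The median of the measured members was 2.55 in OSKM, while the other 4 medians lay between 0.03 and 0.16. In each of the 4 trophoblast-factor pools 7 of 18 trophoblast stem genes were at least 4-fold higher, and none was in OSKM. In GETM these were the introduced Gata3, Tfap2c and Eomes together with Hand1, Gjb3, Bmp8b and Wnt7b (Wnt7b was named after its values were seen). Hand1, a trophoblast transcription factor, was 26.2 FPKM in GETM and 0.504 FPKM in MEF. At least 2-fold lower were 3 trophoblast stem genes in GTMS, GETM and GETMS in ESC medium, 5 in GETMS in TSC medium and 6 in OSKM, and the list medians lay between -0.35 and 0.65. Among 8 differentiated trophoblast genes, the placental lactogen Prl3d1 was 302 FPKM in GETMS in TSC medium, 77.5 in GETM and 0.313 in MEF, and Plac1 was 73.2 FPKM in GETM and 0.192 in MEF. The imprinted genes had medians between -0.14 and -0.03, with single large differences such as Phlda2, a regulator of placental growth, at 0.357 FPKM in MEF and 128 to 456 FPKM in the 4 pools.

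Proliferation genes had medians of 1.53 in OSKM, 1.2 in GTMS, 1.00 in GETM, 1.21 in GETMS in ESC medium and 0.74 in GETMS in TSC medium. Those of ribosome biogenesis and Myc targets were 1.00, 1.41, 1.20, 1.46 and 1.43 in the same order, and those of cytokine genes -1.52, -1.55, -1.20, -1.75 and -2.52. Interferon response genes differed in direction, with medians of 0.02, 0.62, -1.49, -0.85 and -1.58. Markers of other cell types had medians of -2.94, -1.97, -2.31, -2.32 and -1.96, with 6, 6, 7, 7 and 7 of 10 at least 2-fold lower and 0, 3, 1, 1 and 0 at least 2-fold higher. The macrophage lysozyme Lyz2 was 566 FPKM in MEF and 8.21 to 24.2 FPKM in the pools. In all, 698 of 11913 genes were at least 4-fold apart from MEF in OSKM (309 higher, 389 lower), 718 in GTMS (371 and 347), 681 in GETM (257 and 424), 833 in GETMS in ESC medium (371 and 462) and 989 in GETMS in TSC medium (375 and 614). With a pseudocount of 0.1 the counts were 1115 for GTMS and for GETM, 1313 for GETMS in ESC medium and 1516 in TSC medium, and with a filter at a mean FPKM of 5 they were 446 for OSKM, 459 for GTMS and 443 for GETM. The largest single differences were mostly small RNA genes such as Snord49b and Mir24-1 that were listed at 0 in a pool, for which no fold is given.

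**Figure D1:**
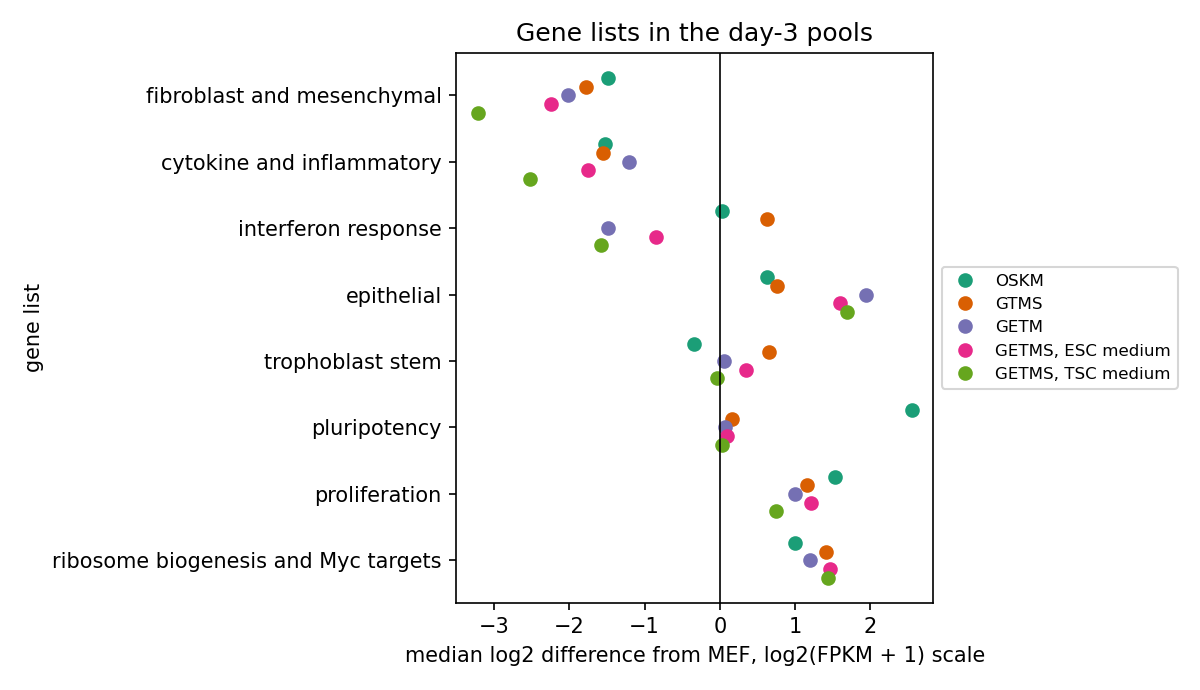
Median difference from MEF (x axis, log2 on the FPKM + 1 scale) of 8 gene lists (y axis) in the 5 day-3 pools, 1 point per pool, without replicates. Fibroblast genes run from -1.48 in OSKM to -3.21 in GETMS in TSC medium, and the pluripotency median of 2.55 in OSKM stands apart from the other pools.

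The GETMS pools in the 2 media were then set against each other and against the smaller factor sets. GETMS in ESC medium and in TSC medium were at least 4-fold apart in 109 genes (57 higher and 52 lower in ESC medium), or 244 with a pseudocount of 0.1. In ESC medium the fibroblast list was 0.99 higher (7 of 37 genes at least 4-fold), with Postn at 35.9 FPKM compared to 4.08 FPKM. The median of the proliferation genes was 0.54 higher and that of the interferon genes 0.57 higher. The connexin Gjb2 was 64.4 FPKM in ESC medium and 2.52 FPKM in TSC medium, and Peg10 was 118 compared to 20.9 FPKM. In TSC medium Prl3d1, Krt8 and Serpine1 were higher, with log2 differences of -3.44, -2.24 and -1.67 (ESC minus TSC medium). Factor genes differed little between the media, and none was 2-fold apart.

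To look at the difference between sets with and without Esrrb, GETMS in TSC medium was set against GETM. The pools were at least 4-fold apart in 90 genes (51 higher and 39 lower in GETMS), or 196 with a pseudocount of 0.1. The fibroblast list had a median of -1.25 and the cytokine list of -0.82, while trophoblast stem genes were at 0.01. Against MEF, the fibroblast median was -2.0 in GETM, -2.2 in GETMS in ESC medium and -3.2 in GETMS in TSC medium. The GETMS pool in ESC medium thus lay closer to GETM on this list. GETMS in TSC medium and GTMS, which lacked Eomes, were at least 4-fold apart in 296 genes (88 higher and 208 lower in GETMS), or 584 with that pseudocount. Of 25 interferon response genes, 16 were at least 4-fold lower (median -2.40), such as Rtp4 at 1.78 compared to 59.9 FPKM. Krt8 was 245 compared to 16.7 FPKM, Postn was 4.08 compared to 83.2 FPKM, and 4 of 16 epithelial genes were at least 4-fold higher. The medium of the GETM and GTMS pools is not stated here, so factor set and medium were not separated in these comparisons. GETMS in ESC medium and OSKM were at least 4-fold apart in 531 genes (253 higher, 278 lower in GETMS), or 895 with that pseudocount. Of 8 differentiated trophoblast genes 5 were at least 2-fold higher in GETMS and 0 lower (median 2.42), of 18 trophoblast stem genes 9 higher and 2 lower (1.28), and of 16 epithelial genes 7 higher and 3 lower (0.92). Of 16 pluripotency genes 5 were higher and 7 lower (-0.67), and of 25 interferon response genes 0 higher and 11 lower (-0.92). The pluripotency and trophoblast stem lists hold factors introduced into these pools. The reference TSCs and ESCs, from other libraries and another kit, were compared over the same 11913 genes. Of these, 641 were at least 4-fold higher in TSC and 324 in ESC. Genes low in MEF and in all day-3 pools, such as Elf5, had been filtered out. These 2 numbers thus leave out part of the distance between TSCs and ESCs and are no full scale for the day-3 differences.

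To follow chromatin opening, the ATAC peak lists of the day-3 pools were compared with those of MEF, iTSC and iPSC. The lists held 44564 peaks in MEF, 156550 in OSKM, 127855 in GTMS, 60633 in GETM, 29491 in GETMS in ESC medium, 74038 in GETMS in TSC medium, 64509 in iTSC and 178115 in iPSC. The 2 shortest lists, of MEF and of GETMS in ESC medium, came from 1 library each and the others from 2. Whether the number of libraries set the length of a list was not tested, and it bears on every share below. The list taken as iPSC is called ESC in its track header and by 1 of the 2 iPSC labels, so it may hold ESC peaks, and every share and count given for iPSC carries this doubt. Of the peaks, 82.1% in OSKM (exact 95% interval 81.9 to 82.3), 78.1% in GTMS, 61.8% in GETM, 43.4% in GETMS in ESC medium and 65.6% in GETMS in TSC medium overlapped no MEF peak. With the 29491 best-scored peaks of every list, these shares were 51.5%, 45.9%, 46.7%, 49.2% and 45.3%, in another order of the pools. Here the MEF, iPSC and iTSC lists were cut too, so some peaks counted as absent overlap a lower-scored MEF peak. The uncut list of GETMS in ESC medium thus went from 12791 to 14509 absent peaks. Of the peaks absent from the full MEF list, the share found in the iPSC list only was 21.7% for OSKM, 19.3% for GTMS, 18% for GETM, 16.9% for GETMS in ESC medium and 18.9% for GETMS in TSC medium. The share in the iTSC list only was 3.00%, 4.43%, 6.87%, 9.70% and 6.37%. With equal numbers of peaks, the order turned in 4 pools, where the share in the iTSC list only was 12.8% (GTMS), 12%, 12.1% and 12.9% and that in the iPSC list only 6.59%, 4.77%, 5.60% and 4.80%, while OSKM kept more iPSC-only peaks (10.8% compared to 6.31%). The cut took more of the iPSC list, with 178115 peaks, than of the iTSC list, with 64509, and this turn was not separated from it. With the better-scored part of each list (50%), again the MEF, iPSC and iTSC lists included, the iPSC-only share of GETMS in ESC medium was 10.4% and the iTSC-only share of OSKM 1.86%. MEF peaks without an overlap in the pool made up 34.9%, 35.1%, 46.1%, 62.2% and 40.6%, and with equal numbers of peaks 49.5%, 44.0%, 45.0%, 49.2% and 43.3%. Each group had 1 list, so there is no replicate check, and the intervals cover counting error only.

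**Figure D2:**
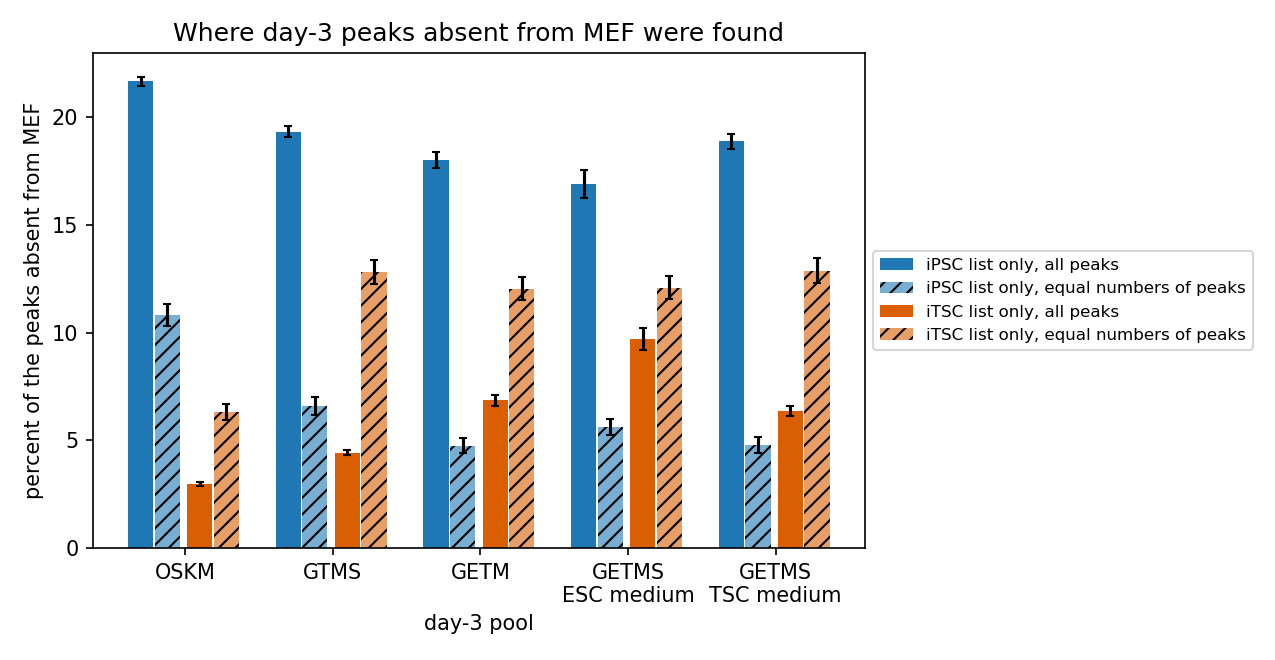
Share of the day-3 peaks absent from MEF (y axis, percent) that overlapped only the iPSC list (blue) or only the iTSC list (orange) in each of the 5 pools (x axis), for all peaks (plain bars) and for equal numbers of best-scored peaks (hatched bars). For the hatched bars the MEF, iPSC and iTSC lists were cut to the same number as well. Bars are 1 list each and lines are exact 95% intervals. With all peaks the iPSC-only share is the higher one in each pool, from 16.9% to 21.7%, and with equal numbers it is the lower one in all pools but OSKM.

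Peaks were also counted at the listed genes, within 5 kb of each gene's span in the day-3 table (mm9 build). Of 32 pluripotency genes, 17 held a peak in MEF, 28 in OSKM, 29 in GTMS, 20 in GETM, 18 in GETMS in ESC medium, 21 in GETMS in TSC medium, 30 in iTSC and 32 in iPSC. Of 26 trophoblast stem genes the numbers were 20, 25, 24, 23, 21, 22, 25 and 26 in the same order, of 30 epithelial genes 25, 29, 30, 29, 20, 29, 30 and 30, and of 38 fibroblast genes 37, 37, 37, 37, 31, 35, 34 and 36. Elf5, a trophoblast stem cell regulator, had 0 peaks in MEF, 5 in OSKM, 7 in GTMS, 5 in GETM, 2 in GETMS in ESC medium, 6 in GETMS in TSC medium and 8 each in iTSC and iPSC. Cdh1 had 0 in MEF, 7 in OSKM, 6 in GETM and 11 in iTSC. Esrrb had 3 in MEF, 2 in GETM, 9 in GTMS, 11 in iTSC and 30 in iPSC. The lists differ in length, and these numbers were not adjusted for it.

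The established iPSC clones were first compared to MEF, to ask which fibroblast and stem cell genes separate them. In GETMS iPSCs all 32 tested pluripotency genes rose. Pou5f1 was 936 ± 86.3 CPM (counts scaled to library size; SD, n = 2) compared to 0.196 in MEF (log2 change 12.10 ± 0.38 SE) and Nanog was 1635 ± 20.4 compared to 1.48 CPM (log2 change 10.08 ± 0.33). Tdh, a threonine dehydrogenase, was 452 CPM, Sall4 322 CPM and Utf1 77.4 CPM. All 3 had no count in MEF, so Tdh was at least 2850-fold, Sall4 at least 2026-fold and Utf1 at least 486-fold higher (against 3 counts over the group). All 38 fibroblast genes fell, such as Cd44 (log2 change -10.62 ± 0.25). Outside this list, Col12a1 was at 917 CPM in MEF and 0.0797 CPM in GETMS iPSCs. Dpt, with no count in the iPSCs, was at least 1165-fold lower. Epithelial genes rose in 27 of 29 cases and fell in 2, with Cdh1 at 460 compared to 0.196 CPM, and 12 of 14 cytokine genes fell while 2 rose, such as Vcam1 (log2 change -9.24). Of the factors used for these clones, Tfap2c rose at least 316-fold and Esrrb by a log2 change of 11.58, while Gata3 and Myc fell (log2 change -1.34 and -2.86).

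Other lists moved less uniformly in GETMS iPSCs. Ribosome biogenesis genes rose in 26 of 28 cases (Fbl by a log2 change of 2.46), proliferation genes in 24 of 28 with 2 that fell (Mcm5 2.24), and germline genes in 21 of 24 with 2 that fell. Germ layer and primed genes rose in 16 and fell in 4 of 22, 2-cell-like genes rose in 5 of 6, and reprogramming factor genes rose in 6 and fell in 2 of 8. The p53 and senescence list had 15 of 20 genes that fell and 2 that rose (Cdkn1a -2.21), the imprinted list 24 and 10 of 37, the extraembryonic endoderm list 12 and 7 of 23, the interferon list 11 and 7 of 22, the other cell type list 8 and 4 of 16, the differentiated trophoblast list 3 and 2 of 6, and the trophoblast stem list 10 and 12 of 26. Sex-linked genes rose in 2 and fell in 1 of 6, and their median of 0.04 changed sign under the other scalings. Adjusted over the list alone, these counts stayed as they were apart from the other cell type list, with 10 genes lower.

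In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 12788 of 17731 genes differed between GETMS iPSCs and MEF (6802 higher, 5986 lower; 6164 of them at least 4-fold). The camera set test called 12 lists, and 4 of these calls held with an estimated correlation, those of the fibroblast (adjusted p = 0.0234), pluripotency (0.0234), cytokine (0.0234) and epithelial (0.0394) lists. The calls lost had an adjusted p of 0.0784 (extraembryonic endoderm), 0.101 (proliferation), 0.116 (ribosome biogenesis and reprogramming factors), 0.158 (p53), 0.178 (imprinted and germline) and 0.195 (germ layer) with an estimated correlation. OSKM iPSCs differed from MEF in 12235 genes (6380 higher, 5855 lower; 5669 at least 4-fold). Again all 32 pluripotency genes rose and all 38 fibroblast genes fell, and 27 of 29 epithelial genes rose. Pou5f1 was 1176 ± 41.2 CPM and Nanog 1136 ± 29.4 CPM, Tdh was at least 4279-fold higher, and Trh, the thyrotropin-releasing hormone gene, was 372 CPM and at least 2345-fold higher. The pluripotency, fibroblast, epithelial and cytokine calls held with an estimated correlation (adjusted p = 0.0282, 0.032, 0.035 and 0.032).

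The question whether iPSCs from GETMS differ from ESCs was addressed against ESC lines BYKE and v6-5. Nanog differed by a log2 change of 0.20 ± 0.20, Esrrb by -0.04, Klf4 by 0.15 and Pou5f1 by 0.42 ± 0.19 (936 compared to 702 CPM), none past the threshold. Of 32 pluripotency genes, 2 rose (Gdf3 by 0.68 and Tdh by 0.61) and none fell (3 and none adjusted over the list alone). The immediate early gene Egr1 showed the largest rise, at 42.5 ± 4.11 CPM compared to 0.761 ± 0.52 CPM in ESCs (log2 change 5.90 ± 0.29, adjusted p = 1.44e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), followed by Fos (3.11), the BMP target Id3 (1.99) and the metallothionein Mt2 (1.61). Nxf3 (-3.32), Sh3bgrl (-2.68), Stk26 (-2.27), Meioc (-2.17) and Galnt7 (-1.89) fell. The 6 tested sex-linked genes had a median of -0.57. Whether the clones and ESC lines differ in sex was not tested. Fibroblast genes fell in 14 of 38 cases (20 lower and 2 higher adjusted over the list alone; camera adjusted p = 4.1e-12, and adjusted p = 0.515 with an estimated correlation). Among them Col1a1 was 2.93 compared to 15.2 CPM, and ESC library v6-5_1 alone held 47.4 CPM, where its sister library held 4.11 CPM. Germline genes fell in 6 of 24 cases, such as Tex19.1 and Cyct (9 adjusted over the list alone; camera adjusted p = 1.57e-04, and adjusted p = 0.515 with an estimated correlation). Imprinted genes fell in 6 and rose in 1 of 37 (8 and 2 adjusted over the list alone) and ribosome biogenesis genes rose in 6 and fell in 1 of 28 (9 and 1), and both camera calls (adjusted p = 0.0133 and 0.00186) had an adjusted p of 0.515 with an estimated correlation.

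The mitochondrial share of the counts was 4.31 to 7.02% in GETMS iPSC libraries and 4.04 to 4.82% in OSKM iPSC libraries. It was 2.65 to 4.18% in the ESC libraries other than v6-5_1, which held 8.86%. In all, 1576 genes differed between GETMS iPSCs and ESCs (843 higher, 733 lower), of which 74 were at least 4-fold apart (10 higher, 64 lower). This count rested on both clones. Without clone C12 1 gene was called (Egr1) and without clone C10 4 genes. It was 147 without library v6-5_1 (where 31 genes under the naming rule lost their call, among them Mt2, Stk26, Meioc, Gdf3, Tdh, Col1a1, Tex19.1 and Cyct), 226 with only these groups in the fit, 787 with each library as a sample and a replicate block, and 2519 without a filter on low counts. The share of higher calls was 53.5% here, 40.2% with DESeq2, 39.5% with relative-log size factors in edgeR and 43.9% without Gm42418 and mitochondrial genes. Of the 45 genes of the naming rule that were called, Egr1 alone kept its call in every alternative run.

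OSKM iPSCs stood farther from the ESCs, with 5685 genes that differed (3036 higher, 2649 lower; 117 and 374 at least 4-fold). Id3 (log2 change 3.87), Trh (3.51; 372 compared to 32.4 CPM), Mt2 (3.34), the imprinted growth factor Igf2 (3.03), Nkx6-2 (2.92) and Gata2 (2.85) rose the most. Xlr3a (-6.94), Nxf3 (-5.31), Rian (-3.88), Zfp981 (-3.77), Meg3 (-3.35) and Cyct (-3.28) fell the most. The 6 tested sex-linked genes had a median of -1.33, and a difference in sex was not tested here either. Meg3 and Rian are non-coding RNAs expressed from the maternal copy of the imprinted Dlk1-Dio3 region. Pluripotency genes rose in 13 of 32 cases with none that fell (14 adjusted over the list alone; adjusted p = 0.366 with an estimated correlation), germline genes fell in 12 of 24 (14 adjusted over the list alone; 0.366), and imprinted genes fell in 12 and rose in 6 of 37 (14 and 7 adjusted over the list alone; 0.366). Trophoblast stem genes rose in 11 and fell in 1 of 26, epithelial genes rose in 10 and fell in 3 of 29 (both adjusted p = 0.366 with an estimated correlation). The number of genes was 3759 without library v6-5_1 and 3729 with only these groups in the fit. Of 60 called genes under the naming rule, 43 kept their call in every alternative.

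Set directly against each other, GETMS and OSKM iPSCs differed in 688 genes (327 higher and 361 lower in GETMS; 84 and 75 at least 4-fold). Egr1 was 42.5 compared to 1.17 CPM (log2 change 5.17 ± 0.27). The Dlk1-Dio3 transcripts Rian (3.53 ± 0.61, adjusted p = 0.0105), Meg3 (3.36 ± 0.56, adjusted p = 0.00901) and Mirg (3.01 ± 0.52, adjusted p = 0.0104 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) were higher in GETMS iPSCs. Meg3 was 206 CPM in GETMS clone C12 and 79.4 in clone C10, 4.84 and 22.8 CPM in OSKM clones C1 and C3, and 164 and 130 CPM in ESC lines BYKE and v6-5. Igf2 (-3.69), Fgfbp1 (-3.38), Ube2l6 (-3.02), Abca1 (-2.96), Gata2 (-2.91) and the imprinted Peg10 (-2.83; 60.9 compared to 432 CPM) were lower. In edgeR's quasi-likelihood test no pluripotency gene of 32 passed (12 had an unadjusted p under 0.05, DESeq2 called 3, and 3 were lower adjusted over the list alone), and the list's camera call (median -0.28) had an adjusted p of 0.297 with an estimated correlation. Trophoblast stem genes fell in 9 of 26 cases (12 adjusted over the list alone; 0.265 with an estimated correlation), fibroblast genes in 7 of 38 (13 adjusted over the list alone; 0.297) and the epithelial keratins Krt8 (-1.88) and Krt18 (-2.36) with 1 further gene of 29 (8 lower and 1 higher adjusted over the list alone; 0.297). The count was 9 without clone C12, 104 without C10, 213 without C3, 446 without library v6-5_1, 1036 with only these groups in the fit, 1086 with each library as a sample and 1696 without a filter on low counts. The calls of Meg3, Rian, Mirg, Igf2 and Peg10 were lost without clone C12 (adjusted p from 0.072 to 0.166), and 1 of 36 called genes under the naming rule, Egr1, kept its call throughout.

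**Figure D3:**
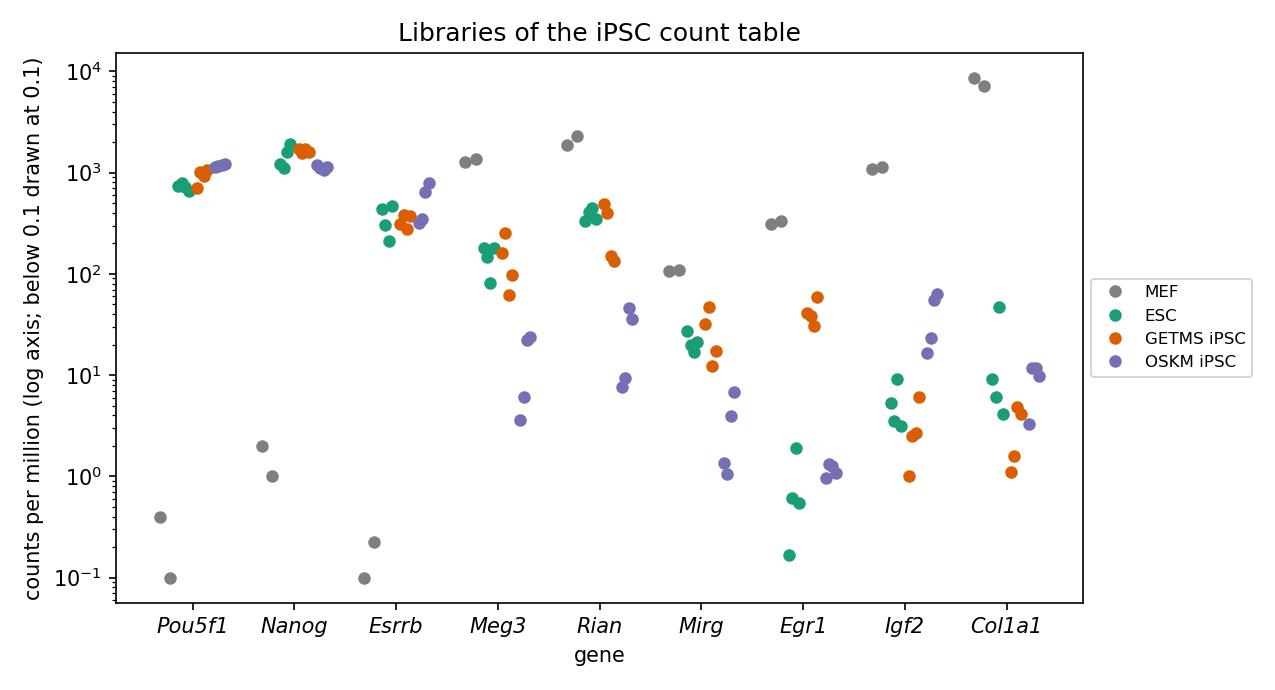
CPM (log y axis, values below 0.1 drawn at 0.1) of 9 genes (x axis) in each library of the iPSC count table, 1 point per library (2 MEF, 4 ESC, 4 GETMS iPSC and 4 OSKM iPSC). Meg3 lies at 3.56 to 23.6 CPM in the OSKM libraries and at 61.3 CPM or more in the ESC and GETMS libraries, and Egr1 is lower in ESC and OSKM than in GETMS libraries.

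The established iTSC clones were compared to MEF in their own table, whose MEF libraries also held trophoblast transcripts. Elf5 was 116 and 20.4 CPM in MEF libraries 1 and 2, compared to 0.198 and 0 CPM in the MEF libraries of the iPSC table. The 7 genes with no count in those MEF libraries and high in every trophoblast library stood here at a median of 22.7% and 9.55% of the trophoblast level, so rises of trophoblast genes against these libraries are not folds against fibroblasts free of such transcripts. Mean levels in the MEF libraries of the iTSC table were 51.5 CPM for Tfap2c, 25.3 CPM for Eomes and 109 CPM for Cdh1, and in those of the iPSC table, scaled separately, 0, 1.5 and 0.196 CPM. Tfap2c rose by a log2 change of 2.90 ± 0.36 in GETM iTSCs (382 compared to 51.5 CPM) and 2.92 in GETMS iTSCs, Eomes by 2.86 and 2.60, Esrrb by 3.07 and 2.64, Gata3 by 1.88 and 1.48, and Cdh1 by 2.83 and 2.87. Elf5 was 224 ± 90.1 CPM in GETM iTSCs (log2 change 1.76, adjusted p = 0.0494 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; up to 0.199 over the alternatives, with the call lost in 4 of 13) and did not pass in GETMS iTSCs (1.53, adjusted p = 0.0781). Bex1 (4.71 and 4.98) and Bex4 (6.62 and 6.59) were among the largest rises. Trophoblast stem genes rose in 20 and fell in 1 of 26 cases in GETM iTSCs and in 19 and 1 in GETMS iTSCs, epithelial genes in 26 and 25 of 30, and differentiated trophoblast genes in 6 of 14 in both. Adjusted over the list alone, trophoblast stem genes rose in 21 cases in both and epithelial genes in 28 and 26. Camera called these lists, but with an estimated correlation they had an adjusted p of 0.133, 0.264 and 0.133 in GETM iTSCs and 0.152, 0.284 and 0.154 in GETMS iTSCs. Of the reprogramming factor genes, Klf4 fell (-2.71 and -3.19).

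Fibroblast genes fell in 37 of 38 cases in GETM iTSCs and in 35 in GETMS iTSCs (37 in both adjusted over the list alone; adjusted p = 0.0652 and 0.0608 with an estimated correlation). Acta2, smooth muscle actin, was 11790 CPM in MEF and 120 ± 96.7 CPM in GETM iTSCs (log2 change -6.62), where library 32 of clone 4F_3 held collagen and actin transcripts far above its sister library (Col1a1 917 compared to 1.61 CPM). In GETMS iTSCs Col3a1 changed by -12.19, and Igsf10 and Lum, with no count there, were at least 2268-fold and 870-fold lower. The mesenchymal regulators Snai2 (-5.90 and -9.64) and Zeb2 (-5.22 and -9.70) fell. Cytokine genes fell in 10 and rose in 1 of 15 cases in GETM iTSCs (12 and 1 adjusted over the list alone; adjusted p = 0.0353 with an estimated correlation) and fell in 11 and rose in 0 in GETMS iTSCs (11 and 2 adjusted over the list alone; adjusted p = 0.0608). Pluripotency genes rose in 15 and 14 of 24 cases, with 1 that fell in each (15 in both adjusted over the list alone), and proliferation genes in 16 of 28 in both (19 and 17). Their adjusted p with an estimated correlation was 0.163 and 0.162 for pluripotency and 0.318 and 0.385 for proliferation. In all, 5320 of 15767 genes differed in GETM iTSCs (2299 higher, 3021 lower) and 5327 in GETMS iTSCs (2407 higher, 2920 lower). The GETM count was 2866 without clone 4F_5, 3029 without 4F_3 and 3430 without MEF library 2.

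The iTSCs were then set against TSCs. Mitochondrial genes took 2.34 to 3.66% of the counts in TSC libraries, 3.86 to 4.92% in GETMS iTSC libraries and 5.12 to 6.09% in GETM iTSC libraries, without overlap between the groups. In GETMS iTSCs the neuronal ubiquitin ligase Trim9 (log2 change 4.36 ± 0.53, adjusted p = 0.0151; 23.1 compared to 1.1 CPM), the transcription factor Klf2 (2.62, adjusted p = 0.0151; 47.9 compared to 7.78 CPM), Syna (2.43), a syncytin of the placenta, Tns1 (2.24), Pdrg1 (1.94) and Gng5 (1.71) rose in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Rps3a3 (-5.22), Hmga1b (-3.83), Slc7a2 (-3.54), Rsph3b (-2.72), Rnf157 (-2.66) and the ERK phosphatase Dusp6 (-1.74) fell. Rps3a3, Hmga1b and Rsph3b have near-identical copies elsewhere in the genome that could share their reads and are uncertain. Of 26 trophoblast stem genes none passed in edgeR (8 had an unadjusted p under 0.05, DESeq2 called 6, and 1 was higher and 4 lower adjusted over the list alone; camera adjusted p = 0.068). Elf5 was 191 compared to 642 CPM (-1.75 ± 0.61, adjusted p = 0.21), Gata3 differed by -0.52, Esrrb by -0.12 and Tfap2c by 0.33. The interferon response list was higher by a median of 1.68 (camera adjusted p = 2.36e-07, and adjusted p = 0.603 with an estimated correlation), with 0 of 27 genes called by edgeR (12 at an unadjusted p under 0.05, 4 by DESeq2, 6 adjusted over the list alone). The 5 tested sex-linked genes had a median of 4.29 here, 2.15 for GETM iTSCs against TSCs and 2.39 for GETMS against GETM iTSCs. Against MEF it was -2.59 for GETM and -0.31 for GETMS iTSCs. Whether the groups differ in sex was not tested, and such a difference cannot be told apart from that between the groups. A total of 47 genes differed between GETMS iTSCs and TSCs (31 higher, 16 lower). The count was 5 without line TSChomo, 16 without TSChetero and 22 without clone 5F_1, and it was 549 with DESeq2, 1020 without a filter on low counts, 2333 with each library as a sample (1809 with a replicate block) and 84 without MEF library 1 and library 32. Of 12 called genes under the naming rule, 1 kept its call in every alternative, the uncertain Rps3a3. The calls of Klf2 and Trim9 were lost without either TSC line (adjusted p up to 0.136 and 0.131) that of Rnf157 without TSChomo (0.0505) and that of Tns1 without library 32. In simulated counts for this comparison, 1 of 100 genes with a 2-fold change and 36 of 100 with a 4-fold change were recovered.

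GETM iTSCs and TSCs differed in 79 genes (72 higher, 7 lower). Those higher were led by D7Ertd443e (log2 change 6.33), Col3a1 (5.47), Col1a2 (5.10), Col12a1 (4.64), Postn (4.52) and Lox (4.32), and 12 of 38 fibroblast genes rose (22 adjusted over the list alone; camera adjusted p = 1.98e-32, and adjusted p = 0.319 with an estimated correlation). Col1a1, chosen after its values were seen, was 1.61 and 917 CPM in libraries 31 and 32 of clone 4F_3, 160 and 12.9 CPM in libraries 51 and 52 of clone 4F_5, and 5.00 to 51.9 CPM in the TSC libraries. Klf2 (2.67) and Syna (2.16) rose, and Limch1 (-2.59), Ephb3 (-2.02), Klf5 (-1.98; 75.2 compared to 297 CPM), a regulator of trophectoderm, and Mfge8 (-1.61) fell. No trophoblast stem gene of 26 passed in edgeR (8 at an unadjusted p under 0.05, 1 by DESeq2, 1 lower adjusted over the list alone; camera adjusted p = 0.0884), and Elf5 was 224 compared to 642 CPM (-1.52 ± 0.60, adjusted p = 0.325). Interferon genes were higher by a median of 1.83 with none of 27 called in edgeR (12 at an unadjusted p under 0.05, 4 by DESeq2, 5 adjusted over the list alone; camera adjusted p = 6.85e-08, and adjusted p = 0.58 with an estimated correlation). The count was 45 without library 32 (where Col3a1, Col1a2, Col12a1, Postn, Lox, Syna and Mfge8 were among 10 genes under the naming rule that lost their call), 10 without line TSChetero and, in edgeR, 0 without TSChomo, where 1166 genes had an unadjusted p under 0.05. It was 462 with DESeq2, 834 without a filter on low counts and 1382 with each library as a sample (924 with a replicate block), and 0 of 16 called genes under the naming rule kept their call in every alternative.

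GETMS and GETM iTSCs differed in 75 genes, 4 higher and 71 lower in GETMS. Trim9 was 23.1 compared to 0.148 CPM (log2 change 7.19 ± 0.64, adjusted p = 0.00718 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and Aff3 also rose (1.93). Fibroblast genes fell in 15 of 38 cases (25 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.53e-67, and adjusted p = 0.0919 with an estimated correlation), with Col3a1 (-6.96), Col5a2 (-5.76), Col1a1 (-5.66) and Acta2 (-5.52). Fbln5 (-5.58), which is not in this list, fell as well. The summed level of the fibroblast list was 4062 CPM in GETM library 32 and 253 CPM in its sister library 31, 1342 and 583 CPM in libraries 51 and 52, and 251 to 593 CPM in the GETMS libraries. Cytokine genes fell in 2 of 15 cases (Vcam1 by -4.21 and Cxcl12 by -4.09; 5 adjusted over the list alone; 0.178 with an estimated correlation) and imprinted genes in 2 of 36 (Rian by -4.68 and Gab1 by -1.80; 4 lower and 1 higher adjusted over the list alone; 0.144). No trophoblast stem gene of 26 passed in edgeR or in DESeq2, and 0 had an unadjusted p under 0.05. Without library 32, 13 of the 14 called genes under the naming rule lost their call in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Lost in this test were Col3a1 (-5.36, adjusted p = 0.628), Col5a2, Col1a1, Acta2, Fbln5, Vcam1 (-3.35, 0.828), Cxcl12 (-2.71, 0.598), Rian (-3.31, 0.841), Gab1 (-1.84, 0.215) and Aff3 (1.97, 0.196), among others. The count was 4 without library 32, 19 without clone 4F_3, 26 without 5F_1, 114 without 4F_5 and 1 without 5F_2, which was Trim9. It was 6 with only these groups in the fit, 7 without MEF library 1 and library 32, 201 with each library as a sample, 223 with DESeq2 and 388 without a filter on low counts. Trim9 kept its call in every alternative run, the only one of 14 called genes under the naming rule that did.

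**Figure D4:**
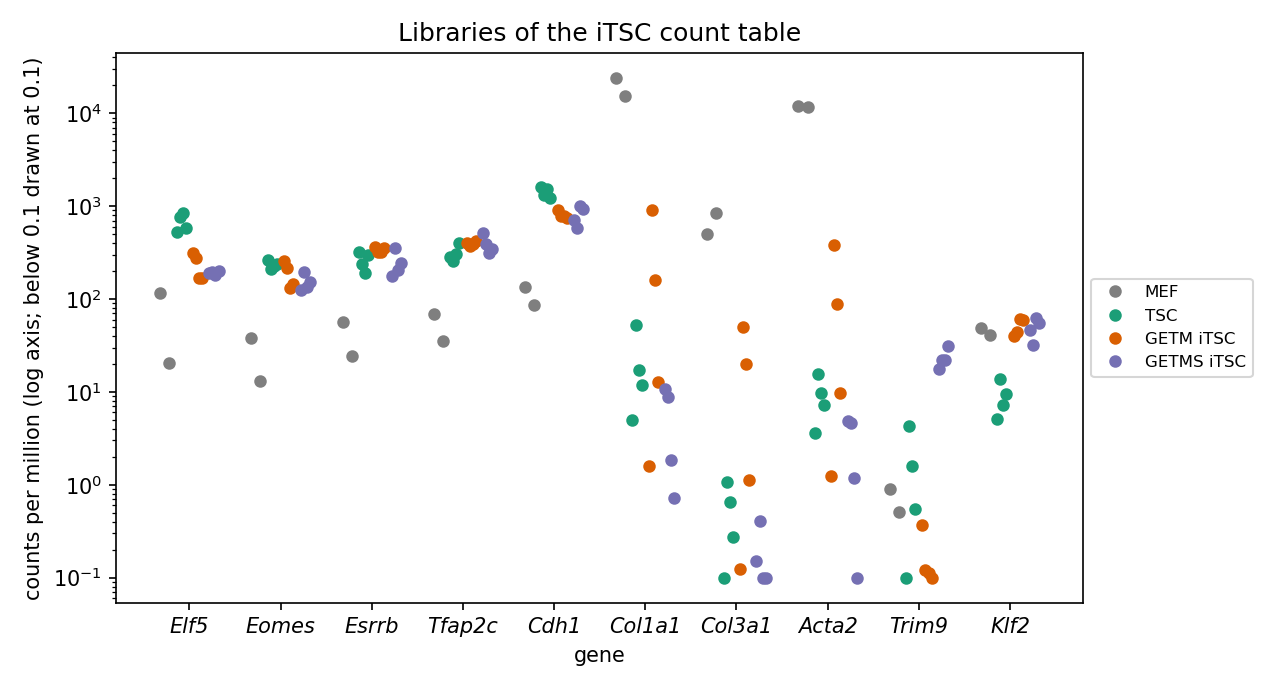
CPM (log y axis, values below 0.1 drawn at 0.1) of 10 genes (x axis) in each library of the iTSC count table, 1 point per library (2 MEF, 4 TSC, 4 GETM iTSC and 4 GETMS iTSC). Elf5 is 20.4 and 116 CPM in the MEF libraries, Col1a1 reaches 917 CPM in a GETM library, and Trim9 is higher in the 4 GETMS libraries than in the others.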

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

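Groups of 4 libraries were compared on several measures of depth, composition and marker levels, which gave 54 comparisons of a group on a measure. In 0 of these was a library far enough from the others to pass Dixon's critical value, and chance would give 2.7. The measures are related and the groups hold pairs of libraries from the same clone or line, so both numbers are rough guides. Library 32 was not flagged, although its summed fibroblast level was 4062 CPM compared to 253 CPM in its sister library 31. Of the tests below, those on fibroblast RNA as a source of Meg3, on the Dlk1-Dio3 transcripts and on peaks at Esrrb were chosen only after the result was seen.

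The MEF libraries of the iTSC table held trophoblast transcripts, and library 32 of GETM clone 4F_3 held fibroblast transcripts. All 7 genes that had no count in the other MEF libraries and were high in every trophoblast library were detected (100%), at a median of 22.7% of the trophoblast level in MEF library 1 and 9.55% in library 2, with an interquartile range of the log2 ratio of at most 0.336. Single genes ranged from 18.8 to 50.9% in library 1 and from 7.7 to 16.4% in library 2. Ratios that are mostly even argue against separate expression of these 7 genes by the fibroblasts. RNA or reads mixed in may be the source, and how they came in was not tested. In library 32, 152 fibroblast genes stood at a median of 5.36% of MEF (interquartile range 0.452), and mixing between libraries, leftover fibroblasts and feeder cells stay open there. For library 32 no biological explanation was tested.

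Meg3 and Rian were lower in both OSKM clones than in GETMS clones and ESC lines. Fibroblast RNA could raise Meg3, but the fibroblast share supplied at most 2.58% of it in any ESC line or GETMS clone. In a fit without the ESC libraries, the smaller difference between the iPSC sets was 3.35 on the log2 scale (highest adjusted p = 0.0263 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That difference holds no ESC library, so its size could hardly change. The fit shows only that the calls did not rest on the spread of the ESC libraries. Silencing of the maternal Dlk1-Dio3 transcripts stays open, since the smallest difference of Meg3, Rian and Mirg (3.01) restates the pattern and the 34 other imprinted genes moved both ways, with 2 called higher and 4 called lower in GETMS clones. With 2 clones per set, the factor set and chance between clones were not separated.

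Esrrb was 18.7 FPKM in the GETM pool, which did not receive it, and this was 11% of its lowest level in the pools that did. Reads carried over from those pools cannot be told apart from other sources, since 0 of 3016 genes high in all of them lay in GETM under 50% of that share, but only 3 besides Esrrb were even 4-fold lower there. Transcription of the locus in GETM cells stays open. The GETM list held 2 peaks there that MEF lacked (mm9 chromosome 12, 87743313 to 87744012 and 87814138 to 87815137), and iTSC, iPSC and the Esrrb-receiving pools GTMS and GETMS in TSC medium held peaks overlapping both, GETMS in ESC medium the second one only. These may reflect either source, as the pooled values do not separate introduced from endogenous Esrrb.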

How the results depend on the processing

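The tests without Gm42418 and mitochondrial genes, without ESC library v6-5_1, without library 32, and without MEF library 1 and library 32 were chosen after the data were seen. Counts of genes for both iPSC sets and for GETMS iTSCs against MEF stayed within 1.5 times under each alternative run, and none of the called genes under the naming rule changed direction. For the counts that moved, given here, the cause was not tested. Libraries held 2778189 to 9163435 counts in the iTSC table and 8488610 to 14218422 in the iPSC table, and of 100 simulated 2-fold changes 0 to 6 and 35 to 53 were recovered per comparison. Whether depth or the spread between clones set this was not tested. The simulations changed only 200 genes each, so these rates may not hold where far more genes were called, as against MEF. No paired analysis was possible for day 3 and ATAC because each group had 1 column or list. For the same reason the limma fit, its replicate block, the fit of only the groups compared and leaving out libraries were not run on day 3, and windows around start sites were replaced by windows around gene spans.

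Without a filter on low counts, 2519 genes were called for GETMS iPSC against ESC, 1696 for GETMS against OSKM iPSC, 834 for GETM iTSC against TSC, 1020 for GETMS iTSC against TSC and 388 for GETMS against GETM iTSC. With DESeq2 the last 3 of these were 462, 549 and 223. With only the groups compared in the fit, the counts were 226 for GETMS iPSC against ESC, 3729 for OSKM iPSC against ESC, 1036 for GETMS against OSKM iPSC and 6 for GETMS against GETM iTSC. With each library as a sample they were 1086 for GETMS against OSKM iPSC, 1382 and 2333 for GETM and GETMS iTSC against TSC and 201 for GETMS against GETM iTSC.

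The library numbers did not pair the samples in a uniform way. Correlations of same-numbered deviations ran from -0.888 to 0.801 in the iPSC table (9 of 21 over 0.1) and from -0.528 to 0.378 in the iTSC table (4 of 21). Values this far from 0 in either direction mean that some lines and clones of the iPSC table shared variation between their libraries. The source of this variation was not tested. With each library as a sample and the replicate block, 787 genes were called for GETMS iPSC against ESC, 924 for GETM iTSC against TSC and 1809 for GETMS iTSC against TSC.

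Without ESC library v6-5_1 the counts were 147 for GETMS iPSC against ESC, 3759 for OSKM iPSC against ESC and 446 for GETMS against OSKM iPSC. Without library 32 they were 45 for GETM iTSC against TSC and 4 for GETMS against GETM iTSC, and without MEF library 1 and library 32 46, 84 (GETMS iTSC against TSC) and 7. Leaving out each clone, line or MEF library in turn gave 1 to 1891 genes for GETMS iPSC against ESC (lowest without C12), 9 to 726 for GETMS against OSKM iPSC (lowest without C12), 2866 to 4112 for GETM iTSC against MEF (lowest without 4F_5), 0 to 81 for GETM iTSC against TSC (lowest without TSChomo, where edgeR gave 1166 genes at an unadjusted p under 0.05), 5 to 57 for GETMS iTSC against TSC (lowest without TSChomo) and 1 to 114 for GETMS against GETM iTSC (lowest without 5F_2).

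With an estimated correlation, camera called 4 lists in place of 12 for each iPSC set against MEF, 0 in place of 4 for GETMS iPSC against ESC, 0 in place of 7 for OSKM iPSC against ESC, 0 in place of 8 for GETMS against OSKM iPSC, 1 in place of 11 for GETM iTSC against MEF, 0 in place of 12 for GETMS iTSC against MEF, and 0 in place of 4, 2 and 6 for GETM and GETMS iTSC against TSC and GETMS against GETM iTSC.

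On day 3, a pseudocount of 0.1 gave 1115 genes at least 4-fold apart from MEF for GTMS and for GETM, 1313 for GETMS in ESC medium and 1516 in TSC medium, 895 for GETMS in ESC medium against OSKM, 244 between the media, and 196 and 584 for GETMS in TSC medium against GETM and GTMS. A filter at a mean FPKM of 5 gave 446 for OSKM, 459 for GTMS and 443 for GETM. With quantile normalization of the FPKM columns, every day-3 count stayed within 1.5 times.

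ATAC shares are given for OSKM, GTMS, GETM, and GETMS in ESC and in TSC medium, in this order. For equal numbers of peaks and for the better-scored part, the MEF, iPSC and iTSC lists were cut as well. Absent from MEF were 83.2, 79.3, 63.5, 45.5 and 67.0% with an overlap of 50% of the smaller peak, 51.5, 45.9, 46.7, 49.2 and 45.3% with equal numbers of peaks, and 79.3, 73.9, 55.2, 33.5 and 59.7% with the better-scored part of each list (50%). In the iPSC list only were 17.9, 15.7, 14.8, 14.4 and 15.8%, then 10.8, 6.59, 4.77, 5.60 and 4.80%, then 21, 18.6, 13.8, 10.4 and 15%. In the iTSC list only were 2.72, 4.24, 6.97, 10.0 and 6.46%, then 6.31, 12.8, 12, 12.1 and 12.9%, then 1.86, 4.11, 6.56, 8.82 and 6.06%. MEF peaks missing from a pool were 39.0, 38.5, 48.5, 63.7 and 43.2%, then 49.5, 44.0, 45.0, 49.2 and 43.3%, then 26.0, 24.2, 37.8, 55.7 and 31.7%.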

Other observations

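GETM and GTMS were not set against each other above. Of 25 interferon response genes measured on day 3, 22 were at least 2-fold lower with GETM than with GTMS and 0 at least 2-fold higher (median log2 difference -2.26, and -2.71 to -2.12 over the other pseudocount, filters and scaling). Isg15 was 2.99 and 50 FPKM and Oasl2 2.8 and 41.0 FPKM, while the MEF pool held 22 and 18.5 FPKM. Both pools lack replicates, and the difference was not tested.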
